A study of Mus musculus with 18 samples.

How the data were processed

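RNA was measured in 18 Affymetrix MOE430_2 arrays, a one-colour platform in which each gene is read by 1 or more probe sets. Tibiae of CD1 mouse embryos at embryonic day 15.5, of both sexes, were grown in organ culture for 6 days. C-type natriuretic peptide (CNP, 1e-06 M) or its vehicle (albumin in dilute acid, 1 mM as the labels give it) was given on days 1, 3 and 5. Per the labels, 24 tibiae were used per treatment. On day 6 each bone was cut under the microscope into its resting/proliferating, hypertrophic and mineralized part, and the pieces of one zone were pooled before RNA was extracted. The 3 zones of a culture therefore come from the same pooled bones, and a culture, not a zone piece, is the independent unit. The titles number the cultures 2, 3 and 4 in each treatment, which makes 6 groups of 3 arrays and 6 cultures, and the series design calls them independent trials.

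Per the series design, the submitters analysed their results with GeneSpring 7.2. The software that turned probe brightness into one value per probe set is not given in the sources used here. The deposited table holds a linear signal intensity for each probe set, from 0 to 20519. The deposited signal was not scaled between arrays: its trimmed mean (2% off each end) ran from 158 to 514 over the arrays, a 3.24-fold range. Of 45101 probe sets in the table, 64 controls were left out. Because the arrays were not on one level, the intensities were quantile-normalized and tested as log2(signal + 16). A fold change is on that scale and understates changes of dim genes. Probe sets whose mean fell in the lowest 40% (a signal below about 63.5) were left out, so that 27022 of 45037 were tested. For arrays, their number limits the precision.

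Gene names came from the platform annotation. Over the 45037 probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none. Of them, 34741 matched the gene table through their gene identifier, and 0 symbols changed. A gene was represented by its brightest probe set that names it alone, which gave 13247 genes, so counts below are of probe sets unless genes are named. Where the probe sets of a named gene disagree in sign, none of the others passed the test in the opposite direction. Another probe set of a called gene may still show little change. With CNP in the hypertrophic zone it differed by 0.13 for Fank1, -0.36 for Spon1 and 0.096 for Egr3, but by -2.07 for Septin4 and 1.66 for Npr3. Groups came from the titles. The array titled vehicle resting/proliferating replicate 4 carries a treatment field that reads CNP; its title was used, and counting it as CNP was an alternative.

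Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over the 27022 probe sets and a call at an adjusted p under 0.05. CNP and vehicle were compared within each zone in one fit of all 18 arrays. CNP averaged over the zones was tested on the means of the 6 cultures, 3 against 3. Zones, and differences of the CNP response between zones, were compared within cultures, with the culture as a block. Errors of log2 fold changes are standard errors of the fit. Whether arrays of the same number deviate together was checked by the correlation, over probe sets, of their deviations from the group means. CNP and vehicle arrays of the resting/proliferating zone did so in each pair (r = 0.187, 0.378 and 0.154), and so did the culture means (r = 0.173, 0.337 and 0.213). No bound was set for this check. Arrays of the same number also share a hybridization day and, for numbers 2 and 3 of this zone, a fluidics run, so a batch may give these correlations. The main fits of these 2 results leave the number out, as do those of CNP in the other zones. Their p-values, counts, list tests and fits with arrays left out are unpaired unless a block is named. For these 2 results, values with the number as a block are given beside them where they differ.

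Gene lists for chondrocyte stages, bone, other cell types and signalling pathways, and the rule for the genes named, were fixed before the data were examined. Lists were tested with camera, which asks whether a list moved more than other genes, with a preset inter-gene correlation of 0.01, and again with an estimated correlation. They were also tested with fry, which asks whether the genes of a list changed in a common direction, without comparing them with other genes. Counts of list members are given over all probe sets tested and as adjusted over the list alone. Per CNP contrast and per zone contrast in vehicle cultures, the rule named the 10 genes that rose most and the 10 that fell most among those past the threshold with the same sign in all 3 numbered pairs. Where fewer than 10 passed, it named the 10 genes with the smallest p. Of each list it named up to 4 members past the threshold with the largest change, or up to 2 with the largest change if none passed. It always named 12 genes of CNP signalling and chondrocyte differentiation, and for averaged and interaction contrasts the 5 with the smallest p. Of the 12, Nppc, which encodes CNP, was below the signal limit and was not tested.

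The scripts were tested on simulated data with known answers: 5 rounds of 200 changed probe sets among 27022. The noise had the spread of each probe set in the arrays, with a part shared within a culture. It was drawn independently for each probe set. For CNP in the hypertrophic zone, 6.4% of the changes of 0.5 on the log2 scale were recovered, 46.8% of those of 1, 82.8% of 1.5 and 92.8% of 2, and 5.92% of the calls were false. For CNP in the resting/proliferating zone the recovered shares were 8%, 48.8%, 79.6% and 93.6%, and in the mineralized zone 6.8%, 41.2%, 82.8% and 92.8%. For the difference of the CNP response between the hypertrophic and resting/proliferating zones they were 0.8%, 12%, 48.4% and 68.8%. Of 500 simulated lists of 20 unchanged genes, 2.8% fell below 0.05 for CNP in the hypertrophic zone, and 50 of 50 lists shifted by 0.5 were found. Genes of a real list can move together (estimated correlation 0.312 for cartilage matrix and SOX factors), which the simulated genes did not. The 2.8% is therefore not the error rate for such lists.

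The run logs of the arrays gave a hybridization date and time, and the dates gave 2 hybridization days (day 1 holds replicate 3, day 2 replicates 2 and 4). Arrays were parted into 5 fluidics runs at gaps between the logged times, so the runs are inferred from the times alone. Days and runs were used as batches. On 4 arrays of replicate 2 (the 3 vehicle zones and the CNP resting/proliferating zone) the log says that the fluidics protocol was aborted. Within a group, arrays correlated at 0.950 to 0.975, and no 2 arrays shared more than 0.333% of their values, so none was taken as a duplicate. Alternatives covered the normalization, the pseudocount, the filter, the variance prior, cross-hybridizing probe sets, the arrays in the fit, the blocks, each array and each replicate number left out, and the contradictory label. Added after seeing the data were fits without the 2 CNP resting/proliferating arrays of highest actin ratio and without the 4 arrays with an aborted log, and list tests under other scalings and with the fluidics run as a block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.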

Results

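Gene expression was measured in cultured E15.5 mouse tibiae after 6 days with CNP, a peptide hormone that stimulates growth of the cartilage growth plate through the cyclic GMP-producing receptor encoded by Npr2, or with vehicle. Each of the 6 groups (3 zones by 2 treatments) held 3 arrays, and median signals of single arrays ran from 39.3 to 174 before normalization. The arrays separated first by zone: the first principal component held 41.9% of the variance over probe sets and the second 21.8%. On the first component the mineralized arrays scored 67.7 to 73.4 and all other arrays below 0. The ratio of the 3' to the 5' probe set of actin, a sign of RNA integrity, was 4.06 ± 1.30 (SD, n = 3) in CNP and 2.70 ± 0.31 in vehicle resting/proliferating arrays (exact permutation p = 0.3, two-sided). It was 2.95 ± 0.85 and 2.28 ± 0.08 in hypertrophic arrays (exact p = 0.1, the smallest that 3 against 3 can give) and 1.76 ± 0.15 and 1.70 ± 0.13 in mineralized arrays (exact p = 0.8). CNP replicates 2 and 4 of the resting/proliferating zone (4.76 and 4.85) and CNP replicate 2 of the hypertrophic zone (3.93) had the highest ratios.

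In the hypertrophic zone Npr3, the receptor that clears natriuretic peptides, rose most, 6.62-fold (log2 fold change 2.73 ± 0.21, SE, n = 3 per group; limma adjusted p = 3.45e-06), from a mean signal of 291 to 2014. Npr2, which encodes the CNP receptor itself, fell by 0.92 ± 0.15 (adjusted p = 0.00374). Also among the strongest rises were Scube3, a secreted CUB and EGF domain protein (2.41 ± 0.22), and Gdf5, a BMP-family growth factor of joint formation (2.21 ± 0.28). They were followed by P2ry14, a receptor for UDP-sugars (2.20 ± 0.29), Fabp7, a fatty acid-binding protein (2.18 ± 0.25), Ptgs2, the inducible cyclooxygenase (1.85 ± 0.27), and Gng4, a G protein subunit (1.75 ± 0.21), with adjusted p-values between 2.09e-05 and 0.00124. The largest falls were in Lmo2, a transcriptional regulator best known from blood and vessel formation (-2.69 ± 0.32), Septin4 (-2.51 ± 0.28) and Chad, the cartilage matrix protein chondroadherin (-2.46 ± 0.28). Below them came Sostdc1, a secreted BMP and WNT antagonist (-2.26 ± 0.33), Svep1 (-2.23 ± 0.28), Trappc9 (-2.02 ± 0.36), Tent5c (-1.94 ± 0.32) and Cd28 (-1.83 ± 0.25), with adjusted p-values between 9.6e-05 and 0.00656. The genes named so far stayed past the threshold whichever single array was left out. Without a whole replicate number, Npr2 and Sostdc1 lost their calls without 2, P2ry14, Sostdc1 and Trappc9 without 3, and Npr2, Ptgs2, Gng4, Trappc9 and Tent5c without 4. Npr2 and Gng4 also lost theirs without normalization, and Npr2 with only the groups compared (adjusted p of up to 0.22 over these settings). Fank1 (1.90 ± 0.44), the troponin Tnnt3 (1.82 ± 0.33), the proton channel Hvcn1 (1.82 ± 0.39), the troponin Tnni1 (-1.89 ± 0.41) and Spon1 (-1.75 ± 0.40) passed with all arrays. Each lost its call without vehicle replicate 2, all but Tnnt3 also without vehicle replicate 4 or CNP replicate 3, Hvcn1, Tnni1 and Spon1 without vehicle replicate 3, and Fank1, Hvcn1 and Tnni1 without CNP replicate 2 (highest adjusted p = 0.153, 0.0505, 0.0925, 0.116 and 0.114).

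In all, 438 probe sets passed in the hypertrophic zone, 141 higher and 297 lower with CNP (limma), of which 216 changed at least 2-fold, 63 higher and 153 lower. An unadjusted p under 0.05 was reached by 3729 probe sets, against 1351 that chance gives. The 438 stand for 331 named genes. The split between higher and lower calls moved with the scaling: centring each array on its median gave 214 higher and 233 lower, and no normalization gave 94 calls, 9 higher and 85 lower, with the median of all tested probe sets at -0.35. With the fluidics run as a block 184 probe sets passed, 151 of them shared with the 438, and with the hybridization day as a block 665 passed. Within day 2 (replicates 2 and 4) 131 passed, and day 1 holds 1 array per group. Without replicate 2 the number was 78, without replicate 4 it was 71, with only the groups compared in the fit it was 155, and without the 4 arrays with an aborted log it was 176. The actin ratio of this zone was 2.95 with CNP and 2.28 with vehicle (exact p = 0.1). The number of calls fell to 222 without CNP replicate 3, 194 without vehicle replicate 2 and 180 without vehicle replicate 4.

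**Figure D1:**
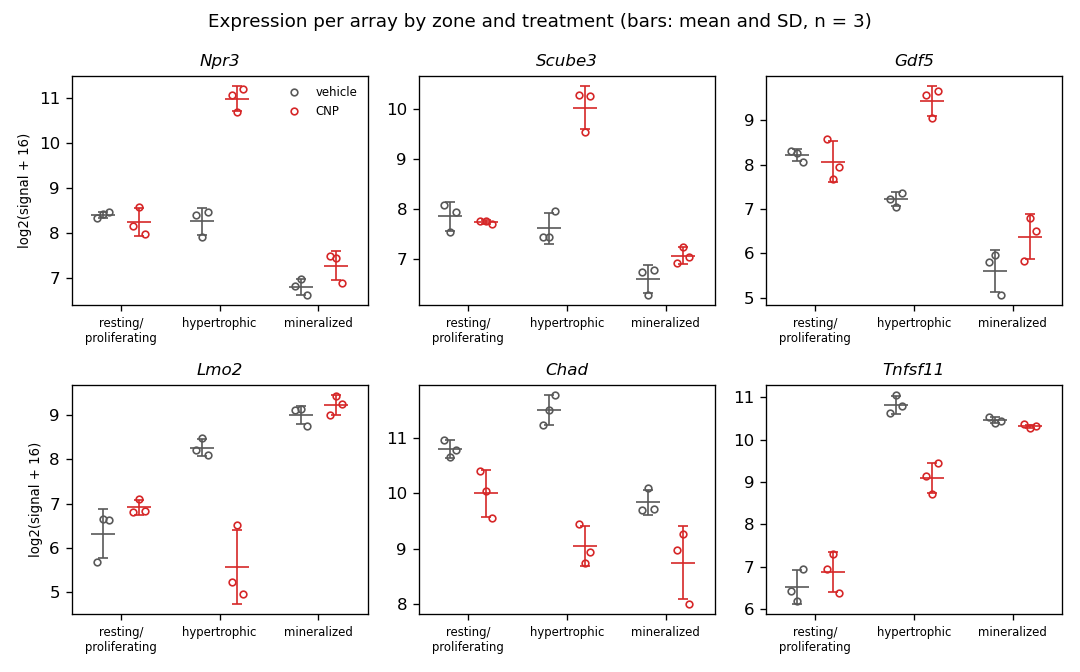
Log2(signal + 16) of 6 genes in each array by zone (horizontal axis) and treatment (grey, vehicle; red, CNP), with bars for the mean and SD of 3 arrays. In the hypertrophic zone Npr3, Scube3 and Gdf5 were higher with CNP (log2 fold changes 2.73, 2.41 and 2.21) and Lmo2, Chad and Tnfsf11 lower (-2.69, -2.46 and -1.72), with no overlap between treatments.

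Several core genes of the growth plate gave no call in that zone. Ihh, the hedgehog ligand of prehypertrophic cells, differed by -0.12 ± 0.24, Col10a1, the collagen of hypertrophic cells, by -0.11 ± 0.44, and the collagenase Mmp13 by -0.19 ± 0.25. Col2a1 differed by -0.08 ± 0.17, Acan by 0.04 ± 0.16 and Sox9 by -0.20 ± 0.27. The growth-restraining receptor gene Fgfr3 differed by -0.02 ± 0.13, the CNP effector kinase Prkg2 by -0.28 ± 0.21 and the p38 kinase Mapk14 by -0.14 ± 0.12. All had adjusted p-values of at least 0.607. Of the list for prehypertrophic and hypertrophic chondrocytes, 1 of 20 measured members rose (Bmp6, 1.29 ± 0.21, which lost its call without replicate 3 or 4 and without normalization) and 0 fell (adjusted over the list alone, 1 rose and 3 fell; camera adjusted p = 0.128). Without replicate 3 that list was called lower (median -0.28, camera adjusted p = 0.0354). Of cartilage matrix and SOX factors, Chad fell and 21 of 22 did not pass (alone, 2 fell, and camera adjusted p = 0.137). Of the list of resting and articular-side chondrocytes, Gdf5 rose, Spon1 and Abi3bp (-1.35 ± 0.22) fell, and 11 of 14 did not pass (alone, 1 rose and 3 fell; adjusted p = 0.962).

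In the list for mineralization and osteoblasts, in the hypertrophic zone, 2 of 16 genes fell with CNP and the median was -0.46 (camera adjusted p = 6.44e-05, and adjusted p = 0.044 with an estimated correlation). Tnfsf11, which encodes the osteoclast differentiation factor RANKL, fell by 1.72 ± 0.23. Cthrc1 fell by 0.53 ± 0.11, and 14 members did not pass (adjusted over the list alone, 4 fell). WNT signalling genes moved the same way (median -0.25 over 17, adjusted p = 0.00122, and adjusted p = 0.044 with an estimated correlation). The WNT antagonists Wif1 (-1.30 ± 0.18) and Dkk1 (-1.05 ± 0.22) fell and 15 did not pass (alone, 6 fell). Of 16 genes of perichondrium, tendon and fibroblasts, Tnc (-0.93 ± 0.19), Col3a1 (-0.75 ± 0.11), Postn (-0.61 ± 0.12) and Dcn (-0.32 ± 0.08) fell and 12 did not pass (alone, 7 fell and 1 rose; median -0.30, adjusted p = 0.00042, but adjusted p = 0.244 with an estimated correlation). Centring each array on its median turned the Dcn difference to 0.0098. Of 14 osteoclast genes the gelatinase Mmp9 (-1.17 ± 0.26) and the integrin Itgb3 (-1.15 ± 0.24) fell (alone, 6 fell; median -0.42, adjusted p = 0.00106, but adjusted p = 0.259 with an estimated correlation). In the same comparison the median of 10 endothelial genes was -0.10 and that of 13 macrophage and leukocyte genes 0.13 (adjusted p = 0.962 for both). Cd68 (-1.07 ± 0.26) was the member that passed (alone, also 1). Tnfsf11 held in every alternative. Wif1, Col3a1 and Abi3bp held without any single array, but Wif1 and Col3a1 were lost without normalization, Col3a1 under median centring and without replicate 4, and Abi3bp without replicate 2 or 4. The calls of Cthrc1, Dkk1, Tnc, Postn, Dcn, Mmp9, Itgb3 and Cd68 were lost without vehicle replicate 2 and, except for Itgb3, without CNP replicate 3. All but Dkk1 and Postn were also lost without vehicle replicate 4, Mmp9, Itgb3, Cd68, Dcn and Dkk1 without CNP replicate 2, Cd68 and Dcn without vehicle replicate 3 and Dcn without CNP replicate 4 (adjusted p of up to 0.195).

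Signalling lists also moved in the hypertrophic zone. The immediate early genes, which answer growth factor and stress signals within minutes, had a median of -0.56 over 19 members (adjusted p = 1.25e-05, but adjusted p = 0.186 with an estimated correlation). Egr2 (-1.41 ± 0.28), Egr3 (-1.34 ± 0.27) and Klf2 (-0.94 ± 0.20) were among 4 that fell. The other probe set of Egr3 differed by 0.096 and that of Egr2 by -1.61. Atf3 rose (0.94 ± 0.23) and 14 did not pass (adjusted over the list alone, 9 fell and 1 rose). In FGF signalling, the feedback phosphatase Dusp6 (-1.54 ± 0.34) and the FGF antagonist Spry4 (-0.91 ± 0.22) fell and 10 of 12 did not pass (alone, 2 fell; median -0.24, adjusted p = 0.0108, but adjusted p = 0.279 with an estimated correlation). In hedgehog signalling, the receptor and target gene Ptch1 (-0.71 ± 0.12) fell and 8 of 9 did not pass (alone, 1 fell; median -0.36, adjusted p = 0.0241, but adjusted p = 0.303 with an estimated correlation). The ER stress list was higher (median 0.37, adjusted p = 0.00438, but adjusted p = 0.244 with an estimated correlation) with 0 of 14 members past the limma threshold (alone, 3 rose). Its largest differences were 1.20 ± 0.34 for Ddit3 (adjusted p = 0.0853) and 0.65 ± 0.36 for Pdia4. Leaving out a replicate number ended the FGF call (adjusted p = 0.0672 without 2 and 0.0709 without 3) and the hedgehog call (0.0566 without 3 and 0.146 without 4). The calls of Egr2, Egr3, Klf2, Atf3, Dusp6 and Spry4, unlike that of Ptch1, were lost without vehicle replicate 2. Ptch1 was lost without replicate 3 or 4, without normalization and under median centring (adjusted p of up to 0.565). All but Klf2 were also lost without vehicle replicate 3, Egr3, Atf3, Dusp6 and Spry4 without CNP replicate 3, Egr2, Klf2, Atf3 and Spry4 without CNP replicate 2, Atf3, Dusp6 and Spry4 without vehicle replicate 4 and Atf3 without CNP replicate 4 (adjusted p of up to 0.149).

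Among the lists that did not move as a whole, the inflammation and prostaglandin list held Ptgs2, 1 of 7 (alone, 1 rose; adjusted p = 0.946). In BMP and TGF-beta signalling the BMP antagonist Grem1 (1.14 ± 0.25) and the activin subunit Inhba (1.05 ± 0.20) rose and 17 of 19 did not pass (alone, 2 rose; adjusted p = 0.962). The natriuretic peptide and cGMP list held the Npr3 rise and the Npr2 fall, with 11 of 13 not past (alone, 1 rose and 1 fell; adjusted p = 0.962). Of the p38 pathway, named in the series title, Mapkapk5, a kinase that p38 activates, rose (0.67 ± 0.16) and 23 of 24 did not pass (alone, 1 rose; adjusted p = 0.962). Ankrd37 (-1.22 ± 0.25) passed in hypoxia and glycolysis, 1 of 15 (alone, 2 fell; adjusted p = 0.43). The serine protease gene Htra1 (-0.62 ± 0.13) passed in matrix proteases and inhibitors, 1 of 17 (alone, 5 fell and 1 rose; adjusted p = 0.225). Tnnt3 and Tnni1 passed in skeletal muscle, 2 of 10 (alone, also 1 rose and 1 fell; adjusted p = 0.946). By limma 0 members passed in cell division (24 genes), glycosaminoglycan synthesis (16), cholesterol synthesis (14), interferon response (9), Schwann cells (6), adipocytes (4) and erythroid cells (1) (alone, 1 fell in cell division and 1 rose in Schwann cells). Their camera adjusted p-values, in that order, were 0.962, 0.962, 0.962, 0.623, 0.0537, 0.986 and 0.962. Without replicate 2 the Schwann cell list was called higher (camera adjusted p = 0.0417). The largest differences in those lists were in Mcm2 (-0.74 ± 0.20), Chst15 (-0.77 ± 0.28), Sqle (-0.37 ± 0.15), Cyp51 (0.37 ± 0.16), Irf7 (-0.75 ± 0.52), Mbp (1.05 ± 0.29), Cebpa (0.54 ± 0.31) and Hba-a1 (-0.16 ± 0.35). Grem1, Inhba, Mapkapk5 and Htra1 lost their calls without vehicle replicate 2 or CNP replicate 3, all but Inhba also without CNP replicate 2 or vehicle replicate 4, and Mapkapk5 and Ankrd37 without vehicle replicate 3, and Ankrd37 without CNP replicate 4 (adjusted p of up to 0.174).

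**Figure D2:**
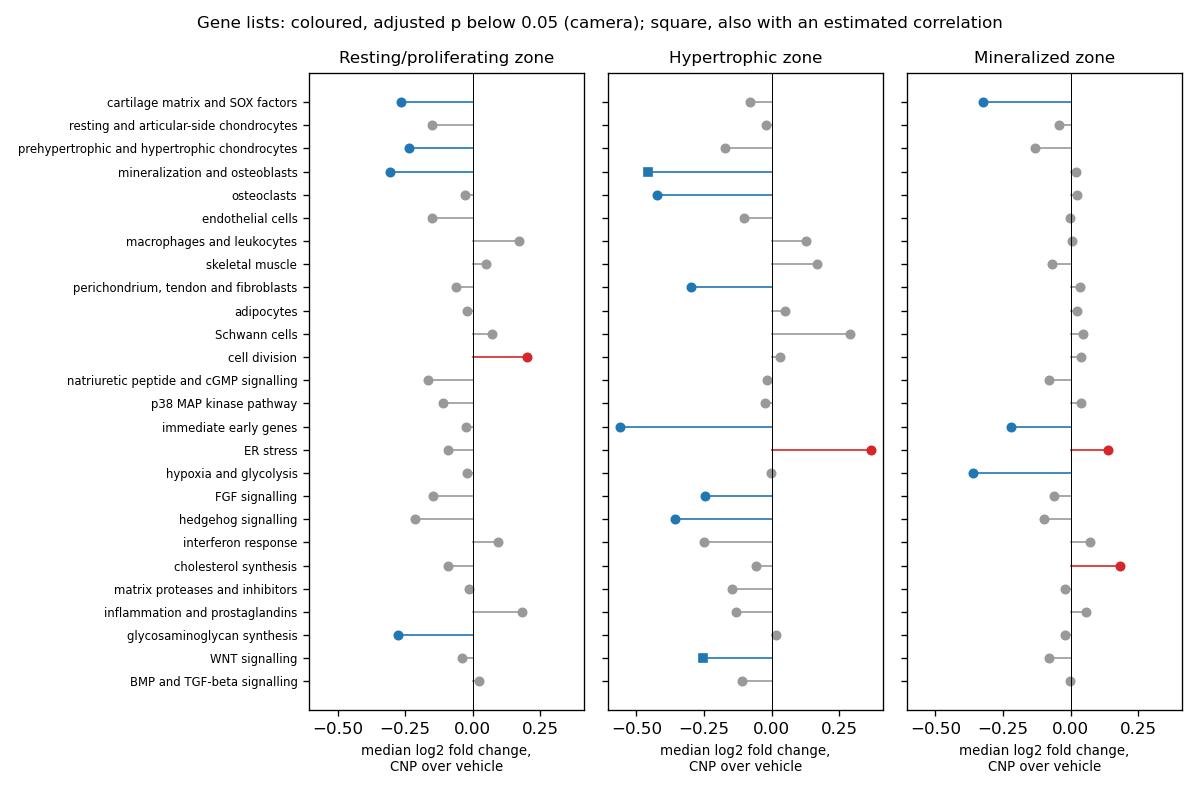
Median log2 fold change (CNP over vehicle) of each gene list (vertical axis) in the 3 zones. Colour marks a camera adjusted p below the threshold (red, higher; blue, lower), and squares mark lists that also passed with an estimated correlation, which were mineralization and osteoblasts (-0.46) and WNT signalling (-0.25) in the hypertrophic zone.

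In the resting/proliferating zone, where chondrocytes divide, few genes passed. Ccdc80, a secreted matrix protein, fell by 0.70 ± 0.09 (SE, n = 3; limma adjusted p = 0.00862). Ibsp, the bone sialoprotein gene (-1.24 ± 0.18, adjusted p = 0.0198), and Lipi, a lipase (-1.83 ± 0.29, adjusted p = 0.0321), fell too. Hacd1, an enzyme of fatty acid elongation, rose by 0.50 ± 0.08 (adjusted p = 0.0462). Just short of the threshold lay Mrpl47 (1.04 ± 0.18, adjusted p = 0.0509) and Gmnn, Map11, Kpna2, Ifi47 and Car8 (1.25, -1.94, 0.67, 1.23 and -1.30, adjusted p = 0.0581 each). With the replicate number as a block these passed, Mrpl47, Kpna2 and Car8 with an adjusted p of 0.0254 and Gmnn, Map11 and Ifi47 of 0.0385, as did Ccdc80 (0.00728), Ibsp (0.0082), Lipi (0.00141) and Hacd1 (0.0339). Npr3 differed by -0.16 ± 0.21 and Npr2 by -0.34 ± 0.15 (adjusted p = 0.815 and 0.39). Sox9, Col2a1, Acan, Ihh, Col10a1, Mmp13, Fgfr3, Prkg2 and Mapk14 lay between -0.48 and 0.28, and none was past the threshold. The list of cell division genes was higher (median 0.20 over 24, camera adjusted p = 0.00181), with Cdk1 at 0.96 ± 0.18 (adjusted p = 0.0597, and 0.0254 with the replicate block) and Bub1 at 0.89 ± 0.26. Lower were cartilage matrix and SOX factors (median -0.27 over 22, adjusted p = 0.00106) and glycosaminoglycan synthesis (-0.27 over 16, adjusted p = 0.00447). So were prehypertrophic and hypertrophic chondrocytes (-0.24 over 20, adjusted p = 0.00783) and mineralization and osteoblasts (-0.31 over 16, adjusted p = 0.00181). The adjusted p with an estimated correlation was 0.44 for cell division, cartilage matrix, glycosaminoglycan synthesis and the hypertrophic list and 0.237 for mineralization, so none of these calls held. By limma 0 of the members of each passed except Ibsp in mineralization (adjusted over the list alone, 2 rose in cell division, and 0, 0, 2 and 5 fell in the others in the order above). Among their members were Chad at -0.80 ± 0.28, Chst15 at -0.87 ± 0.28 and Wnt4 at -0.98 ± 0.39. No other list passed with all arrays. The nearest was the natriuretic peptide and cGMP genes (median -0.16, camera adjusted p = 0.0542, and 0.0296 under median centring). It held Pde9a at -1.05 ± 0.28 and Prkg1 at -0.68 ± 0.13 (limma adjusted p = 0.0692, and 0.0464 with the replicate block). Without replicate 2 the FGF (camera adjusted p = 0.0285), hedgehog and protease lists (0.0265 each) were called lower.

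In all, 7 probe sets passed in this zone, 3 higher and 4 lower (limma), although 3274 reached an unadjusted p under 0.05. With the replicate number as a block, which treats cultures of the same number as pairs, 59 passed, 21 higher and 38 lower. With the hybridization day as a block 46 passed, 16 higher and 30 lower. Within day 2, which leaves out replicate 3, 160 passed, 48 higher and 112 lower, while 0 passed without replicate 2, without replicate 4 or with only the groups compared in the fit (limma; 2043, 1334 and 2329 at an unadjusted p under 0.05). Single arrays decided the number: without CNP replicate 3 it was 912, 319 higher and 593 lower. Without CNP replicate 2 it was 4, without vehicle replicate 3 it was 2 and without vehicle replicate 2 it was 0 (limma). Leaving out CNP replicate 3 keeps the 2 CNP arrays of highest actin ratio. Without those 2, 1 CNP array is left and the spread comes from the other groups, so the number of calls cannot be judged. Without the 4 arrays with an aborted log, 0 passed (limma, 2001 at an unadjusted p under 0.05). Ccdc80 lost its call without vehicle replicate 2, Ibsp also without CNP replicate 2, Lipi without any vehicle array or CNP replicate 4, and Hacd1 without any array but CNP replicate 3 (adjusted p of up to 0.0858, 0.0976, 0.0858 and 0.192). Median centring left 1 call and no normalization 0. Over all settings without calls, 400 to 3350 probe sets had an unadjusted p under 0.05. Counting the vehicle array with the contradictory field as CNP gave 3 calls, 0 of them among the 7. The cell division call was lost without replicate 3 (adjusted p = 0.144) and the hypertrophic list's call without replicate 2 (0.149). Vehicle replicate 2, without which the Ibsp call was also lost, had the highest Col10a1 and Mmp13 values of this zone. Whether another position of its dissection gave the lower Ibsp and lists with CNP was not tested. The actin ratio of this zone was 4.06 with CNP and 2.70 with vehicle (exact p = 0.3).

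In the mineralized zone Mia, a small secreted protein of cartilage, fell by 1.21 ± 0.17 (SE, n = 3; limma adjusted p = 0.0331), from a mean signal of 1083 to 459, and was the gene that passed. The next genes by p were Cetn4 (-1.13 ± 0.19), Cd24a (0.65 ± 0.11), the cartilage proteoglycan gene Epyc (0.91 ± 0.16) and Gm5481 (1.02 ± 0.19). They were followed by Fndc3c1 (0.88 ± 0.20), Uox (0.88 ± 0.21), Fars2 (0.64 ± 0.15), Col9a1 (-0.35 ± 0.08) and Ndufa4l2 (-1.23 ± 0.30). Adjusted p-values of these genes ran from 0.159 to 0.587. Npr3 differed by 0.47 ± 0.21 and Npr2 by -0.26 ± 0.15 (adjusted p = 1 for both). Col10a1, Ihh, Mmp13, Acan, Col2a1, Sox9, Fgfr3, Prkg2 and Mapk14 differed by values from -0.56 to 0.85, also with an adjusted p of 1. Lower as lists were cartilage matrix and SOX factors (median -0.32 over 22, camera adjusted p = 7.96e-08, with Matn1 at -1.19 ± 0.33 and Chad at -1.09 ± 0.28). Hypoxia and glycolysis was lower too (-0.36 over 15, adjusted p = 9.05e-08, with Egln3 at -0.68 ± 0.25 and Ankrd37 at -0.61 ± 0.25), and so were immediate early genes (-0.22 over 19, adjusted p = 0.000873, with Egr3 at -0.53 ± 0.27). Higher were ER stress (0.14 over 14, adjusted p = 0.00531, with Ddit3 at 1.08 ± 0.34 and Hyou1 at 0.74 ± 0.19) and cholesterol synthesis (0.18 over 14, adjusted p = 0.00366, with Insig1 at 0.41 ± 0.25). With an estimated correlation the adjusted p was 0.553 for cholesterol synthesis and 0.418 for each of the other 4 lists, so none of these calls held. By limma 0 members of these lists passed. Adjusted over the list alone 7 cartilage genes fell and 1 rose, 2 ER stress genes rose and 0 passed in the other lists. All other lists had camera adjusted p-values of 0.0823 or more.

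The mineralized zone gave 1 call, with 907 probe sets at an unadjusted p under 0.05, fewer than the 1351 that chance gives. Mia lost its call without vehicle replicate 3, vehicle replicate 4 or CNP replicate 4 (adjusted p of up to 0.18). The number of calls was 2 without vehicle replicate 3 or CNP replicate 2, 4 without CNP replicate 3 and 0 without vehicle or CNP replicate 4, with 549 to 1398 probe sets at an unadjusted p under 0.05 where limma made no call. With the fluidics run as a block 1 other probe set passed and with the day as a block the same 1. Within day 2, 2 passed, and 0 passed without replicate 2, without replicate 4, with only the groups compared or without the 4 arrays with an aborted log. Without replicate 4 the ER stress and cholesterol calls were lost (adjusted p = 0.108 each), and without replicate 2 that of immediate early genes (0.194).

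Averaged over the zones of each culture (3 against 3 cultures), Fabp7 (1.33 ± 0.11, limma adjusted p = 0.0141) and Npr3 (1.01 ± 0.11, adjusted p = 0.0409) rose. Pdgfra, a receptor gene of mesenchymal cells (-0.75 ± 0.07), and Tent5c (-1.10 ± 0.11) fell (adjusted p = 0.0209 each). These were the 4 probe sets that passed, 2 higher and 2 lower, and Chad came next (-1.45 ± 0.17, adjusted p = 0.0515, and 0.0467 with the replicate block), with 3122 at an unadjusted p under 0.05. With the replicate number as a block 35 passed, 7 higher and 28 lower, and with the hybridization day as a block 128. Without normalization 2 others passed, both lower, and median centring gave 2 higher and 1 lower. Within day 2, 27 passed. A culture that lacked a zone was dropped from the means, so leaving out 1 array left out its culture and compared 2 cultures with 3. Without the 4 arrays with an aborted log, which drops both cultures of replicate 2, 0 passed (limma, 1966 at an unadjusted p under 0.05). Without the CNP culture of replicate 3 the number was 9. Without any 1 culture of replicate 2 or 4 it was 0 (limma, 2112 to 2718 at an unadjusted p under 0.05), which ended each of the 4 calls. Tent5c also lost its call without the vehicle culture of replicate 3, and Npr3 without any 1 of the 6 cultures (adjusted p of up to 0.197 and 0.254). Of the 265 genes called in the hypertrophic zone by their representative probe set, 181 (68.3%) had the same sign in the resting/proliferating zone and 190 (71.7%) in the mineralized zone, where sizes were smaller (median absolute log2 fold change 1.00 against 0.21 and 0.16). Zones of a culture share their bones, so chance alone may put this share above 50%.

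The CNP response itself differed between zones for some genes. Between the hypertrophic and the resting/proliferating zone the response of Npr3 differed by 2.89 ± 0.32, of Scube3 by 2.52 ± 0.30 and of Lmo2 by -3.28 ± 0.38 (limma adjusted p = 0.00367 each). That of Enpp6, a phosphodiesterase of choline lipids, differed by -1.76 ± 0.23 and that of Marcks, a protein kinase C substrate, by -1.05 ± 0.14 (adjusted p = 0.00558 each). These calls held without any single array, but all 5 were lost without replicate 3 and without replicate 4, Enpp6 and Marcks also without replicate 2, and all but Npr3 with the fluidics run as a block or without the 4 arrays with an aborted log. Enpp6 and Marcks were also lost with only the groups compared, and Marcks without normalization, under median centring and without an intensity trend. Whether the calls depend on the 2 CNP resting/proliferating arrays of highest actin ratio cannot be judged. Without those 2, that group holds 1 array and the spread comes from the other groups. Marcks had a log2 level of 12.07 in vehicle and 11.04 in CNP arrays of the hypertrophic zone and of 12.13 and 12.15 in the resting/proliferating zone. In all 45 probe sets passed, 15 higher and 30 lower, with 2842 at an unadjusted p under 0.05. No normalization gave 7 higher and 48 lower (median of all probe sets -0.38), and the fluidics run as a block gave 6, of which 3 were among the 45. Without replicate 2 the number was 13, and without replicate 3 or 4 it was 0 (limma; 2324 and 2157 at an unadjusted p under 0.05). It was 2 without the 4 arrays with an aborted log. The number was 96 without CNP resting/proliferating replicate 3 and 15 to 25 without any of vehicle resting/proliferating replicates 2, 3 and 4, vehicle hypertrophic replicates 2, 3 and 4, CNP hypertrophic replicate 3 or CNP resting/proliferating replicate 4.

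Between the mineralized and the hypertrophic zone the response differed in Marcks (1.08 ± 0.14), Lmo2 (2.92 ± 0.38), Septin4 (2.30 ± 0.30), Npr3 (-2.26 ± 0.32) and Tmem119, a membrane protein of osteoblasts and microglia (1.20 ± 0.17), with limma adjusted p-values from 0.00956 to 0.0169. In all 18 probe sets passed, 12 higher and 6 lower, with 2018 at an unadjusted p under 0.05. No normalization gave 5 higher and 6 lower, median centring 8 and 8, and the fluidics run as a block left 0, with 1489 to 1867 at an unadjusted p under 0.05 over all settings without calls. The number was 56 without CNP hypertrophic replicate 4 and 0 without vehicle hypertrophic replicate 2, which ended each of the 5 calls named. It was 2 without vehicle mineralized replicate 2, which ended them too, 1 without the 4 arrays with an aborted log, 0 without any one replicate number, 8 without CNP hypertrophic replicate 2 or vehicle mineralized replicate 4, and 9 without vehicle mineralized replicate 3, vehicle hypertrophic replicate 4 or CNP mineralized replicate 4.

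The zones of vehicle cultures show which genes mark each part of the bone without CNP. From the resting/proliferating to the hypertrophic zone, Ihh rose 6.37-fold (2.67 ± 0.21, SE, n = 3 cultures; adjusted p = 5.64e-07), Col10a1 7.54-fold (2.92 ± 0.45) and Mmp13 6.07-fold (2.60 ± 0.23). Col2a1 (0.22 ± 0.14), Acan (0.32 ± 0.14), Sox9 (-0.11 ± 0.23), Fgfr3 (0.22 ± 0.11) and Mapk14 (-0.06 ± 0.12) did not pass. In the CNP pathway Prkg2, the cyclic GMP-dependent kinase of growth cartilage, rose (1.86 ± 0.19), and Npr2 (-0.03 ± 0.15) and Npr3 (-0.15 ± 0.22) did not pass. The 10 largest rises were in Cd28 (4.97 ± 0.27), Klhl30 (4.75), the homeobox gene Irx5 (4.36), Prkcq (4.33) and Tnfsf11 (4.31), then Ifitm5, a protein of mineralizing osteoblasts (4.30), Tmie (4.27), Hp (4.09), the phosphate regulator Phex (4.02) and Cp (3.98). The 10 largest falls were in Mfap4 (-5.13 ± 0.37), Grem1 (-4.76), Gas1 (-4.56), Pcp4 (-3.88), the angiotensin receptor Agtr2 (-3.61), the WNT antagonist Sfrp5 (-3.52), Abi3bp (-3.49), Apoe (-3.38), 6330403K07Rik (-3.33) and Creb5 (-3.22). Adjusted p-values were at most 1.79e-05 in both sets.

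By list, 11 of 14 resting and articular-side markers fell into the hypertrophic zone and 0 rose (adjusted over the list alone, 12 fell; median -1.80, camera adjusted p = 6.3e-09, and adjusted p = 0.00717 with an estimated correlation). Of 20 prehypertrophic and hypertrophic genes 15 rose and 1 fell (alone, 16 and 1; median 1.02, adjusted p = 4.31e-13, and adjusted p = 0.0102 with an estimated correlation), with Bmp6 at 3.12 ± 0.16 and Bmp2 at 2.50 ± 0.22. Of 16 mineralization genes 11 rose and 2 fell (alone, 11 and 3; median 1.42, adjusted p = 6.46e-07, and adjusted p = 0.00717 with an estimated correlation), with the matrix protein gene Dmp1 at 3.89 ± 0.46. Of 19 immediate early genes 15 rose and 0 fell (alone, 16; median 1.46, adjusted p = 1.14e-13, and adjusted p = 0.00717 with an estimated correlation). Fosb (2.23 ± 0.21), Nr4a2 (1.82), Junb (1.80) and Atf3 (1.76) rose most. Of 24 cell division genes 18 fell and 0 rose (alone, 20; median -0.91, adjusted p = 2.73e-10, but adjusted p = 0.109 with an estimated correlation). Mcm3 (-1.59 ± 0.22), Mki67 (-1.52 ± 0.19) and Top2a (-1.29 ± 0.22) were among them. Of 14 osteoclast genes 10 rose (alone, 10; median 0.84, adjusted p = 1.97e-08, but adjusted p = 0.109 with an estimated correlation), with Mmp9 at 3.71 ± 0.21. Of 9 hedgehog genes 5 fell (alone, 5; median -0.76, adjusted p = 0.000892, but adjusted p = 0.2 with an estimated correlation), with the co-receptors Cdon (-2.53 ± 0.17) and Boc (-1.74 ± 0.18). Of 14 cholesterol genes 4 rose (alone, 9; median 0.41, adjusted p = 0.00021, but adjusted p = 0.215 with an estimated correlation), with Sc5d at 1.03 ± 0.15. Of 7 inflammation genes 2, Ptgs2 (2.74 ± 0.24) and Ptges (2.08 ± 0.23), rose (alone, 2; median 0.54, adjusted p = 0.0116, but adjusted p = 0.109 with an estimated correlation). Of 16 perichondrial genes 7 fell and 3 rose (alone, 9 and 3; median -0.46, adjusted p = 0.0146), with Col14a1 at -3.13 ± 0.21. Of 10 endothelial genes 4 fell (alone, 4; median -0.39, adjusted p = 0.0291), with Cdh5 at -1.16 ± 0.21, which lost its call without normalization (0.0919). For these last 2 lists the adjusted p was 0.375 with an estimated correlation. The perichondrial call was lost without replicate 4 (0.0701) and the endothelial call without replicate 3 (0.0504). Of 104 genes past the threshold that the naming rule picked for these zones, 81 kept their call without any single array and 69 in every alternative. The list members named here were taken from the 81, so they are more stable than their lists.

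In total 5027 probe sets differed between these zones, 2663 higher and 2364 lower in the hypertrophic zone (limma). No normalization gave 2154, 1603 higher and 551 lower, with the median of all probe sets at 0.16. The fluidics run as a block gave 4980. The number was 3180 without vehicle resting/proliferating replicate 4, 3278 without vehicle hypertrophic replicate 2, 3053 without vehicle hypertrophic replicate 4, 3034 and 2206 without replicates 3 and 4 as a whole and 3329 without the 4 arrays with an aborted log. In CNP cultures 6738 probe sets differed, 3358 higher and 3380 lower, the fluidics run as a block gave 3143, and leaving out replicate 3 or 4 as a whole gave 4489 or 3840. No normalization gave 1002 higher and 1966 lower with a median of -0.22.

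**Figure D3:**
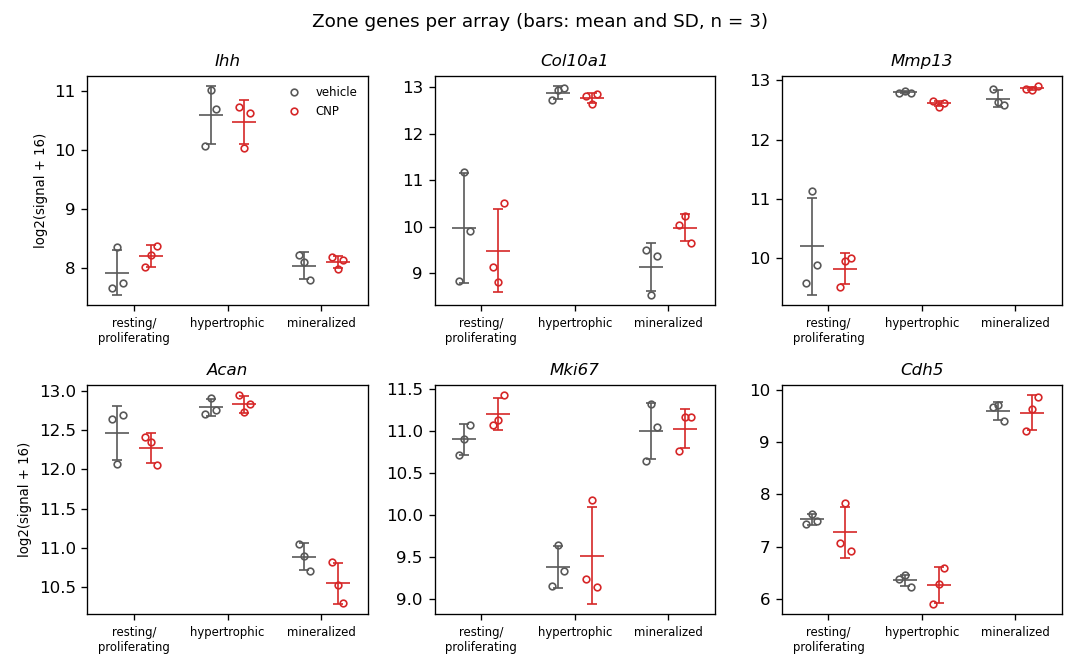
Log2(signal + 16) of 6 genes in each array by zone (horizontal axis) and treatment (grey, vehicle; red, CNP), with bars for the mean and SD of 3 arrays. In vehicle cultures Ihh, Col10a1 and Mmp13 were higher in the hypertrophic than in the resting/proliferating zone (2.67, 2.92 and 2.60), Mki67 was lower there (-1.52), and from the hypertrophic to the mineralized zone Acan was lower (-1.90) and Cdh5, a gene of endothelial cells, higher (3.23).

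From the hypertrophic to the mineralized zone of vehicle cultures, Ihh fell by 2.55 ± 0.21 (SE, n = 3 cultures; limma adjusted p = 6.01e-07). Col10a1 (-3.76 ± 0.45), Acan (-1.90 ± 0.14), Sox9 (-1.43 ± 0.23), Col2a1 (-1.03 ± 0.14) and Fgfr3 (-1.01 ± 0.11) fell as well. So did Npr3 (-1.45 ± 0.22) and Prkg2 (-0.93 ± 0.19), while the probe set used for Mapk14 rose by 0.69 ± 0.12. Only that 1 of the 3 Mapk14 probe sets had this sign, and the lowest differed by -0.36 without passing. Fgfr3 and Prkg2 lost their calls without normalization (adjusted p = 0.0772 and 0.236). Mmp13 (-0.11 ± 0.23) and Npr2 (-0.04 ± 0.15) did not pass. The largest rises were in Ctla2a (4.72 ± 0.28), Tmem178 (4.10), Ocstamp, which osteoclasts need for fusion (4.04), the chemokine receptor Ccr1 (4.02), Igfbp3 (3.90), Gas1 (3.88), Mcam (3.86), Cd34, a marker of vessels and progenitors (3.81), Slc9b2 (3.75) and the macrophage protease Ctss (3.74). The largest falls were in Scrg1 (-6.07 ± 0.33), Prom1 (-5.95), Il17b (-5.26), Epyc (-5.04), Efemp1 (-4.67), Angptl1 (-4.43), Prkcq (-4.33), C1qtnf3 (-4.31), Cth (-4.18) and Col9a2 (-4.12). Adjusted p-values were at most 2.58e-06 in both sets.

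Of 22 cartilage matrix genes 17 fell and 1 rose (adjusted over the list alone, 18 and 1; median -1.70, camera adjusted p = 5.2e-14, but adjusted p = 0.0689 with an estimated correlation), with Matn3 at -4.04 ± 0.16. All 10 endothelial genes measured rose (alone, 10; median 2.13, adjusted p = 1.38e-11, but adjusted p = 0.0689 with an estimated correlation), with Cldn5 at 3.28 ± 0.21 and Cdh5 at 3.23 ± 0.21. Of 14 osteoclast genes 12 rose (alone, 12; median 1.70, adjusted p = 9.94e-11, but adjusted p = 0.0781 with an estimated correlation), with Atp6v0d2 at 3.65 ± 0.22 and Acp5 at 2.70 ± 0.19. Of 13 macrophage genes 11 rose (alone, 11; median 1.78, adjusted p = 3.9e-09, but adjusted p = 0.082 with an estimated correlation), with Cd68 at 3.49 ± 0.27. Of 14 cholesterol genes 13 fell (alone, 13; median -1.29, adjusted p = 1.28e-10, but adjusted p = 0.0689 with an estimated correlation), with Sc5d at -2.41 ± 0.15 and Msmo1 at -1.76 ± 0.11. Of 24 cell division genes 16 rose (alone, 18; median 0.75, adjusted p = 3.36e-07, but adjusted p = 0.169 with an estimated correlation), with Mki67 at 1.63 ± 0.19. Of 17 proteases and inhibitors 12 rose and 1 fell (alone, 12 and 1; median 0.65, adjusted p = 8.2e-05, but adjusted p = 0.178 with an estimated correlation), with Mmp23 at 2.13 ± 0.32. The hypertrophic list held 9 falls and 1 rise among 20 (alone, 10 and 2; median -0.40, adjusted p = 0.000145, but adjusted p = 0.104 with an estimated correlation). Glycosaminoglycan synthesis held 7 falls and 1 rise among 16 (alone, 8 and 3; median -0.26, adjusted p = 0.00211, but adjusted p = 0.35 with an estimated correlation), with Has2 at -3.00 ± 0.18 and Papss2 at -2.34 ± 0.14. Adipocyte genes rose in 3 of 4 (alone, 3; median 1.62, adjusted p = 0.00211, but adjusted p = 0.0689 with an estimated correlation), with Fabp4 at 3.12 ± 0.19. Schwann cell genes fell in 2 of 6 (alone, 4; median -0.68, adjusted p = 0.0228, but adjusted p = 0.104 with an estimated correlation), with Pmp22 at -1.36 ± 0.13. Mineralization genes rose in 6 of 16 (alone, 7; median 0.36, adjusted p = 0.0228, but adjusted p = 0.104 with an estimated correlation), with Ifitm5 at 1.58 ± 0.21. Perichondrial genes rose in 8 and fell in 2 of 16 (alone, 8 and 2; median 0.39, adjusted p = 0.0254, but adjusted p = 0.398 with an estimated correlation), with Col12a1 at 2.19 ± 0.24. FGF signalling genes rose in 7 and fell in 1 of 12 (alone, 7 and 1; median 0.88, adjusted p = 0.0322, but adjusted p = 0.375 with an estimated correlation), with Spry4 at 1.94 ± 0.24. These last 2 calls were lost without replicate 2 (adjusted p = 0.0547 and 0.0587), and those of mineralization and perichondrium also under median centring (0.21 and 0.104). Of 114 genes past the threshold that the naming rule picked here, 99 kept their call without any single array and 92 in every alternative, and the list members named were taken from the 99.

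In total 6386 probe sets differed between these zones, 3127 higher and 3259 lower in the mineralized zone (limma). No normalization gave 4125 higher and 528 lower, with the median of all probe sets at 0.43, and the fluidics run as a block gave 4938 in all. No single array left out moved this number by more than 1.5 times, but without replicate 3 as a whole it was 3645 and without replicate 4 it was 3518. In CNP cultures 8812 probe sets differed, 4307 higher and 4505 lower. No normalization gave 5448 higher and 883 lower with a median of 0.45, median centring gave 3481 higher and 5960 lower, and the fluidics run as a block gave 8882.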

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

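The test that asks whether CNP resting/proliferating replicate 3 holds vehicle tissue was chosen only after the result was seen, and so was the bound used to judge the test of RNA integrity. The CNP response differed between zones in an interaction test, which is what marked the following results. Between the hypertrophic and the resting/proliferating zone 45 probe sets passed, led by Npr3 (2.89), Lmo2 (-3.28), Scube3 (2.52), Enpp6 (-1.76) and Marcks (-1.05). Between the mineralized and the hypertrophic zone 18 passed, led by Marcks (1.08), Lmo2 (2.92), Septin4 (2.30), Npr3 (-2.26) and Tmem119 (1.20).

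In the hypertrophic zone the lists of mineralization (median -0.46, 2 of 16 members past the threshold, adjusted p = 0.044 with an estimated correlation) and of perichondrium (-0.30, 4 of 16, but adjusted p = 0.244 with an estimated correlation) were lower with CNP, which a smaller share of non-cartilage tissue or another position of the dissection could also give. If CNP pieces held less of all other tissue, the medians of the 5 other cell type lists should all lie below 0: skeletal muscle lay at 0.17 (95% interval over genes -0.28 to 0.31), macrophages at 0.13 (-0.25 to 0.28), endothelial cells at -0.10 (-0.32 to 0.19), erythroid cells, with 1 gene, at -0.16 and perichondrium at -0.30 (-0.75 to -0.05), so 2 medians went against it with intervals that hold 0, and the test could not tell. A piece with less of the mineralized side should give a slope below 0 when the CNP effect is set against the difference between the mineralized and the hypertrophic zone, and the slope was -0.121 on average (-0.0785, -0.134 and -0.151 with a replicate held out). That fits such a piece and may equally be CNP acting on the genes that mark the zone, and both zone differences together accounted for 2.28% to 7.31% of the variance over genes. The slope toward the resting/proliferating side was 0.0504 on average (-0.014, 0.0648 and 0.1 with a replicate held out), so more of that side could not be told.

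In the resting/proliferating zone 7 probe sets passed with all arrays and 912 without CNP replicate 3, where RNA integrity or a mix of tissue may play a part. The actin ratio was high in CNP replicates 2 and 4, and the response of these replicates over that of replicate 3 correlated at -0.0319 with the matching difference in the hypertrophic zone and -0.0325 in the mineralized zone. The rule written before the test would exclude this explanation at any value below 0, so by that rule it is excluded. The bound was moved after the value was seen, because the comparison rests on 1 array and the mineralized zone gave the same value, and with the moved bound the test could not tell. Over genes called in the hypertrophic zone, the mean response in the hypertrophic direction was 0.122 ± 0.021 (SE over 265 genes) in replicate 3. By the rule written for that version this excluded vehicle tissue. Once the genes were chosen without the replicate tested, it was 0.0984 ± 0.0411 (75 genes) in replicate 3. It was then 0.123 ± 0.0935 in replicate 2 and 0.27 ± 0.0839 in replicate 4, and that version could not tell. Each value compares 1 CNP with 1 vehicle array, and its error is over genes that may move together. Such an error holds no spread between arrays, so neither version can exclude vehicle tissue.

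In the hypertrophic zone 184 probe sets passed with the fluidics run as a block, so the run might be the cause of part of the difference. Of 148 probe sets called without the arrays of run 4, 132 (89.2%) had the same sign within that run, with a median signed log2 difference of 0.83. Most of these probe sets thus differed in the CNP direction without a difference of run. The check sets 1 CNP array (replicate 2) against 1 vehicle array (replicate 4), which also differ in culture and actin ratio (3.93 and 2.28). With 1 array on each side it cannot exclude the run as the whole cause or as a part.

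Each count was also set against the 10 ways to split the arrays into groups of the same sizes, which cannot give a share under 0.05. For CNP in the resting/proliferating zone the real split gave 7 and the highest other 14, so 2 of 10 splits gave as many. These splits, like the main fit, ignore the pairing of that zone's arrays by number. With the replicate number as a block the real labels gave 59, and exchanging the labels of replicate 2, 3 or 4 gave 3, 0 and 0. The 4 labellings cannot give a share under 0.25. In the mineralized zone they gave 1 and 4, and 2 of 10 gave as many. In the hypertrophic zone the real split gave 438 and the highest other 1, and 1 of 10, the real one, gave as many. That was so too for CNP averaged over the zones (4 and 0), both interactions (45 and 1, 18 and 0) and the zones of vehicle (5027 and 0, 6386 and 0) and CNP cultures (6738 and 0, 8812 and 0). The splits for the average ignore the replicate number, and those for the zones ignore that zones share cultures. Paired labellings were run only for the resting/proliferating zone.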

How the results depend on the processing

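The fits without the 2 CNP resting/proliferating arrays of highest actin ratio and without the 4 arrays with an aborted log, and the list tests under median centring, no normalization and the fluidics run as a block, were chosen only after results were seen. Below, RP, H and M are the resting/proliferating, hypertrophic and mineralized zones, "mean" is CNP averaged over zones, and unmarked zone names are CNP contrasts. No count moved by over 1.5 times with pseudocounts 1 or 64, a robust prior or a 1.5-fold limit. For arrays, signal over background limits dim genes, which the filter leaves out. The run block and the contradictory array give no value for the mean, and the day block was fitted for CNP contrasts. For the mean, an array left out takes its whole culture with it. The cause of the changes below was not tested.

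Replicate number as a block: RP 59, H 674, M 2 and mean 35. It changed no list call. In H the number is not shown to pair the arrays (correlations of deviations -0.0179, 0.0911 and 0.123). In M each array correlated best with its own number, as in RP, but less strongly (0.137, 0.118 and 0.0621). M was not treated as paired, and no bound had been set for that choice. The H-RP interaction had 26 with no replicate block and the M-H interaction 30 with a replicate block in place of the culture.

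Counts by setting. No filter on dim probe sets: RP 4, M 4, mean 2. Lowest 60% left out: RP 28. No normalization: RP 0, H 94, M 0, mean 2, zones H-RP 2154 in vehicle and 2968 in CNP, M-H interaction 11. Median centring: RP 1, M 0, and Dcn in H turned to 0.0098 (adjusted p = 0.987). No intensity trend: RP 1, M 0, mean 2, H-RP interaction 17. Without cross-hybridizing probe sets: RP 4. Groups compared alone: RP 0, H 155, M 0, zones H-RP in CNP 4301, interactions 7 and 6. Fluidics run as a block: H 184, zones H-RP in CNP 3143, interactions 6 and 0. Day as a block: RP 46, H 665, mean 128. Contradictory array as CNP: RP 3, zones H-RP in vehicle 3178, H-RP interaction 19. Without the 2 arrays of high actin ratio: RP 2, zones H-RP in CNP 2620, H-RP interaction 0. Without the 4 aborted arrays: RP 0, H 176, M 0, mean 0, zones H-RP in vehicle 3329, interactions 2 and 1. Where limma made no call, 400 to 3350 (RP), 549 to 1398 (M), 1247 to 2718 (mean), 1674 to 2324 and 1489 to 1867 (interactions) probe sets had an unadjusted p under 0.05.

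Leaving out arrays or replicate numbers gave RP 0 to 912, H 71 to 609, M 0 to 4, mean 0 to 27, zones H-RP 2206 to 3984 in vehicle and 3840 to 6253 in CNP, zones M-H 3518 to 5226 in vehicle and 6194 to 8030 in CNP, and interactions 0 to 96 and 0 to 56. List medians ranged, in RP, prehypertrophic -0.29 to -0.16, cell division 0.15 to 0.32, FGF -0.21 to 0.0283, hedgehog -0.29 to -0.10, proteases -0.21 to 0.16; in H, prehypertrophic -0.28 to -0.0408, Schwann 0.26 to 0.40, FGF -0.37 to -0.20, hedgehog -0.37 to -0.29; in M, immediate early -0.31 to -0.14, ER stress 0.10 to 0.16, cholesterol 0.17 to 0.21. Zones H-RP: endothelial -0.44 to -0.41, perichondrium -0.61 to -0.33, p38 -0.00907 to 0.16. Zones M-H: perichondrium 0.26 to 0.45, immediate early 0.24 to 0.48, FGF 0.83 to 0.93. Some lists gained a call. Without replicate 2 these were RP FGF (camera adjusted p = 0.0285), hedgehog and proteases (0.0265 each), H Schwann (0.0417) and zones M-H immediate early (0.0403). Without replicate 3 they were H prehypertrophic (0.0354) and zones H-RP p38 (0.0315).

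Lists whose call was lost with an estimated correlation (medians): RP cartilage -0.27, prehypertrophic -0.24, mineralization -0.31, cell division 0.20, glycosaminoglycans -0.27. H osteoclasts -0.42, perichondrium -0.30, immediate early -0.56, ER stress 0.37, FGF -0.24, hedgehog -0.36. M cartilage -0.32, immediate early -0.22, ER stress 0.14, hypoxia -0.36, cholesterol 0.18. Zones H-RP osteoclasts 0.84, endothelial -0.39, perichondrium -0.46, cell division -0.91, hedgehog -0.76, cholesterol 0.41, inflammation 0.54. Zones M-H cartilage -1.70, prehypertrophic -0.40, mineralization 0.36, osteoclasts 1.70, endothelial 2.13, macrophages 1.78, perichondrium 0.39, adipocytes 1.62, Schwann -0.68, cell division 0.75, FGF 0.88, cholesterol -1.29, proteases 0.65, glycosaminoglycans -0.26. The RP and M lists were lost with fry too. Fry added H Schwann 0.29 and zones H-RP Schwann 0.10, p38 0.0909 and BMP -0.0665. In zones M-H it added resting 0.11, muscle -0.17, immediate early 0.30, interferon -0.38 and inflammation 0.0898. There it also called the natriuretic and BMP lists higher, although their medians were -0.0424 and -0.0308 (means 0.31 and 0.32). Of all probe sets, 18.6% were called for zones H-RP and 23.6% for zones M-H in vehicle. A fry call there does not show that a list moved more than other genes.

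Lost without cross-hybridizing probe sets: H FGF -0.24, M ER stress 0.13, zones H-RP endothelial -0.33, zones M-H FGF 0.62. Median centring lost H hedgehog -0.38, zones M-H mineralization 0.14 and perichondrium 0.24, and gained RP natriuretic -0.21. The run block lost H FGF -0.16 and hedgehog -0.30, M immediate early -0.14 and ER stress 0.12, and gained H cartilage -0.18. No normalization lost M ER stress 0.11 and cholesterol 0.13, zones H-RP endothelial -0.34 and zones M-H mineralization 0.18, and gained H Schwann 0.34 and zones M-H muscle -0.14. List values under median centring and no normalization are medians after subtracting the median of all probe sets. Without normalization the subtracted median was -0.35 in H, -0.37 in M, 0.16 for zones H-RP and 0.43 for zones M-H.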

Other observations

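The values in the last 2 paragraphs were chosen only after results were seen. Some genes of lists that did not move as a whole differed between the zones of vehicle cultures (SE, n = 3 cultures, limma). From the resting/proliferating to the hypertrophic zone the WNT antagonist gene Dkk1 rose by 3.23 ± 0.22 and Sfrp2 fell by 2.58 ± 0.21, with 5 of 17 WNT genes higher and 6 lower. Car9, which encodes a carbonic anhydrase of hypoxic cells, fell by 2.77 ± 0.31, and the MAP kinase phosphatase gene Dusp1 rose by 2.21 ± 0.13.

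From the hypertrophic to the mineralized zone 2 phosphodiesterase genes of the cyclic GMP list rose, Pde9a (3.10 ± 0.25) and Pde2a (2.03 ± 0.15). The prostaglandin receptor gene Ptger4 (2.51 ± 0.23) and the BMP pathway genes Grem1 (2.37 ± 0.20) and Smad6 (2.13 ± 0.21) rose, and the WNT target Axin2 fell by 1.56 ± 0.18.

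In the resting/proliferating zone Col10a1 had log2 values of 11.19, 8.82 and 9.90 in vehicle replicates 2, 3 and 4 and 8.81, 9.14 and 10.50 in CNP replicates. Mmp13 had 11.13, 9.58 and 9.89 in vehicle and 9.95, 9.52 and 10.00 in CNP replicates.

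Over genes called in the hypertrophic zone without the replicate scored, the mean deviation from the zone mean in the CNP direction was -0.0942, -0.0923 and -0.114 in vehicle resting/proliferating replicates 2, 3 and 4 and 0.029, 0.00615 and 0.157 in CNP replicates. Vehicle replicate 4 is the array whose treatment field reads CNP.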
